A study of Escherichia coli and Aquifex aeolicus with 29 samples.

How the data were processed

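The products of in vitro cleavage of FF and MBP dsRNA by purified RNase III were sequenced from libraries with a custom 3' adapter that, per the labels' protocols, holds a stretch of 15 random bases. Whether these bases were used to remove duplicate molecules is not given in the sources used here. Bowtie 1.1.1 and SAMtools are named in the submitters' processing notes, with no role stated. Adapter trimming, the reference used and the limits on read length are likewise not given in the sources used here. Each of the 22 deposited tables holds, per the file headers, a total number of reads, a number of skipped reads, and a count of reads for each length from 6 to 25 nt. The deposited counts are not normalized. In all 22 tables the counts and the skipped reads add up to the total. A further deposited column, headed as a percentage, holds the fraction of total reads (skipped reads included) at each length, and equals count over total to within 5e-07. It was used only for this check.

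Tables were matched to samples by name. The 18 tables of substituted enzymes each carry the title of 1 sample, followed by a number whose meaning is not stated. It goes with the shortest length kept: the 9 tables with 8 begin at 8 or 9 nt, the 2 with 6 at 7 nt, and the 5 with 3 and the 2 with 2 at 6 nt. The wild-type tables, named as holding all lengths, have no such number, so tables of wild type and variants may have been filtered differently. The 4 wild-type tables name the enzyme and substrate with no replicate number, although the labels list 11 wild-type samples among the 29 samples of the series. Whether each wild-type table is 1 library or several pooled is not stated, so it was taken as the authors' value for its group, with no replicate spread. All tables list the same 20 lengths, but the shortest length with any read differed (6, 7, 8 or 9 nt), with exact zeros below it even in the table of 3102662 reads. The 21 to 23 nt share and the mean length depend on this limit, so each was also computed over the 17 lengths from 9 to 25 nt, a setting added after the tables were seen.

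Shares were taken over the counted reads of 6 to 25 nt, without skipped reads. For each table the most frequent length, the mean length, and the shares of set lengths and classes were computed, with 95% Wilson intervals. Ratios to the wild-type share carry counting error only. A class above 25 nt had been planned and could not be formed from these lengths, and the class planned as 24 to 26 nt holds 24 and 25 nt. PCR reads are not independent molecules, so intervals cover counting error only. Where no read was seen, the limit given is 3 reads over the total counted. Total reads were 84 to 3102662 per table. In the tables with most reads the counting interval of a share is narrow (5.94 to 6.09% at 22 nt for E38 on MBP), whereas 4 tables had under 5000 reads.

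Tests were fixed before the data were examined. For E38, E65 and Q165 of the E. coli enzyme, the 6 pairs of tables that differ only at that residue (3 backgrounds on 2 substrates, 12 different tables) were compared with an exact sign-flip permutation test of the mean difference, two-sided, for the mean length and the 21 to 23 nt share, with Benjamini-Hochberg adjustment over the 6 tests. The variant labelled EEQ was read as the triple variant. Pairs of one background on FF and MBP may share an enzyme preparation, in which case these p-values are too small. The 3 backgrounds alone allow no p under 0.25. The 7 E. coli and 4 A. aeolicus variants were compared with an exact permutation test of the enzyme labels, and the substrates with an exact sign-flip test over the 11 variants, each adjusted over 2 outcomes. A result was called past the threshold at an adjusted p under 0.05. The agreement of FF and MBP profiles was tested by permuting the pairing of variants (100000 resamples, or all pairings within one enzyme). The lengths named in the text follow a rule set in advance: the most frequent length of each table, shares at 14, 21, 22 and 23 nt and the length classes, and per comparison the 3 lengths with the largest mean gain and loss.

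The sign-flip test was run on simulated pairs of tables drawn from the wild-type E. coli profile on FF with added spread between reactions. In 200 simulations, 5 percentage points were added to the 21 to 23 nt share over 17 lengths, and the mean estimate was 4.87 points. An unadjusted p under 0.05 was reached in 100% of them, against 2.5% with nothing added. All simulated tables came from the same profile, whereas the real pairs spanned several backgrounds and both substrates. Over 9 to 25 nt the real differences had SDs of 2.56 to 3.40 percentage points. The E65Q165 tables held only 605 (FF) and 1124 (MBP) counted reads. These rates therefore describe the simulated pairs, and not the power or error of the test on the real tables. Alternatives tried were other length windows, weighting by nucleotides, the median, other classes and scales, single substrates, leaving out EEQ, single pairs or single variants, and, added later, the 9 to 25 nt window, leaving out shallow tables or the E. coli E65 table on MBP, and pairs of equal shortest length. Analyses were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.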

Results

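RNase III is the bacterial endonuclease that cuts both strands of double-stranded RNA (dsRNA). The study asked at which sites the enzymes of Escherichia coli and of the thermophile Aquifex aeolicus cut long dsRNA, and how substitutions at named residues change the cleavage. Purified enzymes were incubated for 30 min with 500 ng of dsRNA carrying either a firefly luciferase sequence (FF) or a maltose-binding protein sequence (MBP), at 37 °C for the E. coli enzymes and at 60 °C for the A. aeolicus enzymes. The small RNA products were then sequenced. The deposited tables used here give the number of reads at each product length from 6 to 25 nt, and hold no positions along the substrates, so the results below are on product length. There were 22 tables, 14 of E. coli and 8 of A. aeolicus enzymes, 1 for each of 11 enzyme variants on each substrate. The E. coli variants were the wild type, the single variants E38, E65 and Q165, the double variants E38Q165 and E65Q165, and a variant labelled EEQ, read here as carrying changes at all 3 residues. The A. aeolicus variants were the wild type, E37, E64 and Q161.

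Total reads per table ran from 84 to 3102662, with a median of 121939. Of the E. coli tables, E65Q165 held 630 reads on FF and 1143 on MBP, and every other one held at least 54235. Of the A. aeolicus tables, E64 held 84 reads on FF and 2880 on MBP. Each variant had 1 table per substrate and no replicate of its own, so single values carry only 95% Wilson intervals, which cover counting error and not the spread between reactions. The wild-type values are the authors' deposited profile for the group, for which the labels list 4 samples (E. coli on FF), 3 (A. aeolicus on FF) or 2 (each enzyme on MBP). The tables also differed in the shortest length they kept. Reads began at 6 nt in 11 tables, at 7 nt in 2 (E. coli E65), at 8 nt in 7 (both E38Q165, both E65Q165, both EEQ, and E38 on FF) and at 9 nt in 2 (A. aeolicus E64). For this reason each tested comparison is also given over 9 to 25 nt, the window that every table kept, which was chosen after the tables had been examined.

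The wild-type E. coli enzyme produced mainly short fragments, with a most frequent length of 12 nt on both substrates. Products of 12 nt made up 22.1% of reads on FF and 20.9% on MBP, and the mean lengths were 11.02 nt and 11.07 nt. Fragments of 21 to 23 nt, the length of small interfering RNAs, were rare: 1.20% of reads on FF (95% interval 1.13 to 1.28%) and 0.578% on MBP (0.535 to 0.623%). At 22 nt alone the wild type had 0.538% and 0.243% of its reads. The wild-type A. aeolicus enzyme peaked 1 nt lower, at 11 nt, which took 23.1% of reads on FF and 30.6% on MBP. Its mean lengths were 10.29 nt and 10.61 nt, and 21 to 23 nt products made up 0.276% and 0.260% of reads. Over all variants, 12 nt was the most frequent length in 11 of the 14 E. coli tables, and 11 nt in 5 of the 8 A. aeolicus tables, with 12 nt in the other 3. The E. coli exceptions were Q165 on FF at 9 nt, EEQ on FF at 13 nt, and E65 on MBP at 7 nt.

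**Figure D1:**
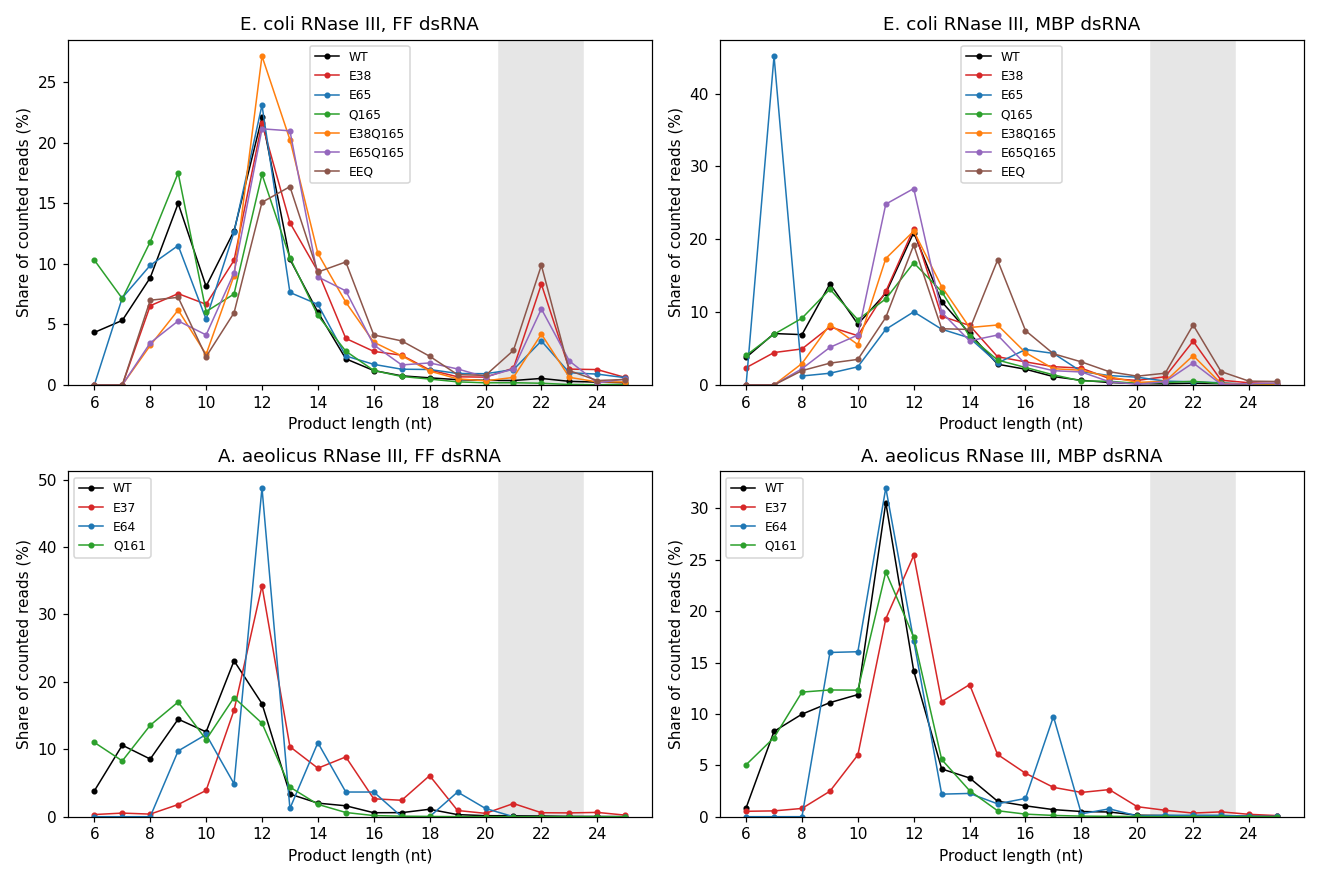
Share of counted reads (%, vertical axis) at each product length (nt, horizontal axis) for every enzyme variant (coloured lines, 1 table each) on FF and MBP dsRNA. The grey band marks 21 to 23 nt. The wild-type E. coli enzyme peaks at 12 nt and the wild-type A. aeolicus enzyme at 11 nt, a separate 22 nt peak stands out in the E. coli tables with an E38 change, in both E65Q165 tables and in E65 on FF, and 45.1% of the reads of E. coli E65 on MBP are 7 nt long.

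Substitution at E38 of the E. coli enzyme went with longer products and a larger peak at 22 nt. The wild type had a small one, with 1.76 times (FF) and 1.84 times (MBP) the mean of 20 and 24 nt. The single E38 variant had 8.32% of its reads at 22 nt on FF (95% interval 8.14 to 8.51%) and 6.01% on MBP (5.94 to 6.09%), which was 15.5-fold and 24.7-fold the wild-type share. The E38Q165 variant had 4.20% on FF and 4.03% on MBP, and EEQ had 9.88% and 8.23%. Tables of enzymes that differed only at E38 were paired (wild type with E38, Q165 with E38Q165, and E65Q165 with EEQ, each on both substrates). The spread over these pairs includes differences between backgrounds and substrates. No variant had a second table on the same substrate, so the spread between reactions alone was not measured. The 21 to 23 nt share was higher with the substitution in 6 of 6 pairs, by 6.38 ± 2.40 percentage points (SD, n = 6 pairs, exact sign-flip test, two-sided p = 0.03125, adjusted p = 0.0625). The mean length was greater in 6 of 6 pairs as well, by 1.87 ± 0.82 nt (SD, n = 6 pairs, exact p = 0.03125, adjusted p = 0.0625). The p of 0.03125 is the smallest that 6 pairs allow, and after adjustment over the 6 tests neither result passed 0.05.

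Over 9 to 25 nt the E38 differences were 6.74 ± 2.56 percentage points and 1.49 ± 0.54 nt (SD, n = 6 pairs each, 6 of 6 higher, exact p = 0.03125), and in that window both passed with an adjusted p of 0.0469. The lengths that gained most over all lengths were 22 nt (4.99 ± 1.64 percentage points), 15 nt (4.04 ± 3.37) and 14 nt (2.13 ± 1.77), each higher in 6 of 6 pairs. The lengths that lost most were 9 nt (−4.96 ± 4.54, lower in 5 of 6 pairs), 7 nt (−3.67 ± 3.28) and 6 nt (−3.35 ± 3.90). The last 2 were lower in 4 of 6 pairs, and they fall below the shortest length kept in part of the tables. Only the pair of wild type and E38 on MBP kept both lengths in both tables, with −2.608 percentage points at 7 nt and −1.405 at 6 nt. In the other pairs the values at these lengths reflect the length limit. Among the 3 pairs whose tables kept the same shortest length, the 21 to 23 nt share was higher in 3 of 3, by 6.56 percentage points on average. These were wild type to E38 on MBP and both pairs of E65Q165 with EEQ, which rest on E65Q165 tables of 630 and 1143 reads. Without the tables under 5000 reads the E38 differences were 6.45 percentage points and 2.17 nt, each higher in 4 of 4 pairs. That is fewer pairs than a p under 0.05 needs.

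Substitution at E65 also went with more 21 to 23 nt products. The single E65 variant had 3.63% of its reads at 22 nt on FF (95% interval 3.57 to 3.70%), 6.75-fold the wild-type share, but 0.432% on MBP (0.380 to 0.491%), 1.78-fold the wild type (0.806% and 2.72-fold, 2.29 to 3.24, over 9 to 25 nt). On MBP its 22 nt reads were no peak, at 0.75 times the mean of 20 and 24 nt against 1.84 for the wild type. E65Q165 had 6.28% at 22 nt on FF (4.61 to 8.50%, 38 reads) and 3.02% on MBP (2.17 to 4.20%, 34 reads). Across the pairs of enzymes that differed only at E65 (wild type with E65, Q165 with E65Q165, and E38Q165 with EEQ), the 21 to 23 nt share was higher in 6 of 6 pairs, by 5.43 ± 3.39 percentage points (SD, n = 6 pairs, exact p = 0.03125, adjusted p = 0.0625). The mean length was greater in 5 of 6 pairs, by 1.36 ± 1.23 nt (SD, n = 6 pairs, exact p = 0.0625, adjusted p = 0.0938). The exception was E65 on MBP, whose mean length of 10.65 nt lay 0.42 nt below the wild type's 11.07 nt because 45.1% of its reads were 7 nt long.

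Over 9 to 25 nt the E65 differences were 5.91 ± 3.35 percentage points and 1.46 ± 0.58 nt (SD, n = 6 pairs each, 6 of 6 higher, exact p = 0.03125), and both passed with an adjusted p of 0.0469. The largest mean gains over all lengths were at 7 nt (4.31 ± 16.98 percentage points), which was higher in only 2 of 6 pairs, at 22 nt (3.64 ± 2.20) and at 15 nt (3.51 ± 3.26), each of these last 2 lengths higher in 6 of 6. The largest losses were at 9 nt (−6.70 ± 5.21, lower in 5 of 6 pairs), 6 nt (−3.75 ± 3.79) and 8 nt (−2.86 ± 4.84). No table with the E65 change kept 6 nt reads, so the 6 nt loss reflects the length limit. Without the pairs that rest on the shallow E65Q165 tables, the 21 to 23 nt share was higher in the remaining 4 of 4 pairs, by 5.21 percentage points, and the mean length by 0.832 nt in 3 of 4, fewer pairs than a p under 0.05 needs. The E38 and E65 comparisons share tables (the wild type, Q165, E38Q165, E65Q165 and EEQ) and are therefore not independent of each other.

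Substitution at Q165 showed no common direction. The Q165 variant alone had 0.361% of its reads at 21 to 23 nt on FF (95% interval 0.319 to 0.408%) and 1.02% on MBP (1.00 to 1.04%), a value below the wild type on FF and above it on MBP. Added to E38, the Q165 change went with a lower 21 to 23 nt share, 5.45% against 11.02% on FF and 4.71% against 7.79% on MBP. Added to E65, it went with a higher share, 9.59% against 5.91% on FF and 3.56% against 1.26% on MBP, where the higher values come from the tables of 630 and 1143 reads. Over the 6 pairs the difference was −0.51 ± 3.43 percentage points (SD, n = 6, exact p = 0.75, adjusted p = 0.75), with 3 of 6 pairs higher, and over 9 to 25 nt −1.07 ± 3.40 (exact p = 0.5, adjusted p = 0.531). The mean length differed by 0.47 ± 1.05 nt (SD, n = 6, exact p = 0.406, adjusted p = 0.488), and over 9 to 25 nt by −0.18 ± 0.67 nt (exact p = 0.531, adjusted p = 0.531), so that its sign depended on the window. Without the E65Q165 tables the differences were −2.26 percentage points and −0.18 nt (4 pairs).

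By length, the largest gains with Q165 were at 13 nt (4.69 ± 4.85 percentage points) and 15 nt (2.96 ± 1.99), both higher in 6 of 6 pairs, and at 12 nt (1.88 ± 8.24, higher in 2 of 6). In the 9 to 25 nt window the gains were 3.76 ± 5.51 at 13 nt (5 of 6 pairs) and 2.62 ± 1.74 at 15 nt (6 of 6). The largest losses were at 7 nt (−9.18 ± 17.93), 8 nt (−0.91 ± 3.63) and 10 nt (−0.63 ± 2.89), each smaller than its SD. At 7 nt only the pairs of wild type and Q165 kept that length in both tables, with 1.81 percentage points on FF and −0.097 on MBP.

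**Figure D2:**
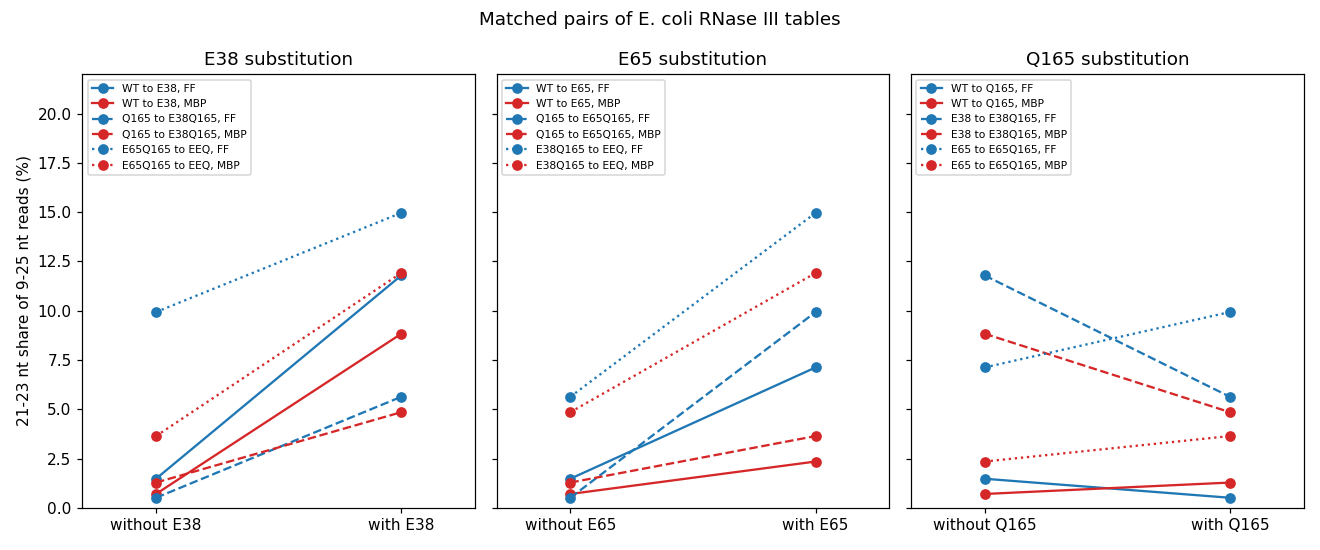
Share of 21 to 23 nt products among 9 to 25 nt reads (%, vertical axis) in E. coli tables without and with each substitution. Each line joins 1 matched pair on FF (blue) or MBP (red), with the line style giving the background. All 6 lines rise for E38 and for E65, and 3 of 6 rise for Q165.

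In A. aeolicus RNase III the single substitutions were compared with the wild type on each substrate. The E37 variant made longer products. Its mean length was 13.26 nt on FF and 12.97 nt on MBP, 2.98 nt and 2.36 nt above the wild type (2.13 nt and 1.73 nt over 9 to 25 nt). Its most frequent length was 12 nt where that of the wild type was 11 nt, and 12 nt products took 34.2% of reads on FF and 25.4% on MBP. The E37 gains were largest at 12 nt (14.4 percentage points, mean of both substrates), 14 nt (7.13) and 13 nt (6.78), and the losses at 9 nt (−10.6), 11 nt (−9.32) and 7 nt (−8.91). Products of 21 to 23 nt made up 3.11% of reads on FF (95% interval 3.01 to 3.20%) and 1.45% on MBP (1.39 to 1.51%), 11.3-fold and 5.56-fold the wild-type share. At 22 nt E37 had 0.589% and 0.353% of its reads, and on FF the share at 21 nt, 1.95%, was above that at 22 nt.

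The Q161 variant made slightly shorter products, with a mean of 9.58 nt on FF and 10.12 nt on MBP, 0.71 nt and 0.49 nt below the wild type (0.40 nt and 0.29 nt over 9 to 25 nt). Its most frequent length stayed at 11 nt. Products of 18 to 25 nt made up 0.071% and 0.133% of its reads, which was 0.038-fold and 0.091-fold the wild-type share. The gains were largest at 6 nt (5.69 percentage points), 8 nt (3.58) and 9 nt (1.89), and the losses at 11 nt (−6.10), 7 nt (−1.47) and 15 nt (−0.963), each in the same direction on both substrates. The E64 variant gave few reads. On MBP its most frequent length was 11 nt (32.0%), its mean length over 9 to 25 nt was 11.67 nt against 11.36 nt for the wild type, and its 21 to 23 nt share was 0.418% (0.239 to 0.729%, 12 reads). On FF its 82 counted reads held none of 21 to 23 nt, which allows a share of up to 3.66%, so no difference from the wild type was detectable there. Its mean gain was largest at 12 nt (17.5 percentage points), 17 nt (4.23) and 14 nt (3.73), 17 and 14 nt being higher on only 1 substrate each and 12 nt by 32.0 on FF and 2.95 on MBP (on FF only over 9 to 25 nt), and its losses at 7 nt (−9.46), 8 nt (−9.27) and 11 nt (−8.41, lower on FF only) include lengths that its tables did not keep. With 2 pairs per substitution no exact p under 0.5 was possible, so these are values of these tables and no test of the variants.

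Across variants, the E. coli enzymes were compared with the A. aeolicus enzymes, each variant taken as the mean of its FF and MBP tables. The 21 to 23 nt share averaged 5.57 ± 4.43% (SD, n = 7) for E. coli and 0.692 ± 1.06% (SD, n = 4) for A. aeolicus, a difference of 4.88 percentage points that did not pass (exact permutation test, two-sided p = 0.0606, adjusted p = 0.121). The mean length was 12.39 ± 1.36 nt (SD, n = 7) against 11.35 ± 1.48 nt (SD, n = 4), which also did not pass (exact permutation p = 0.273, adjusted p = 0.273). In the 9 to 25 nt window the differences were 5.35 percentage points (exact permutation p = 0.0545) and 1.28 nt (exact permutation p = 0.0697), adjusted p = 0.0697 for each. With the wild types and single variants alone, as A. aeolicus has no double variants, they were 2.95 percentage points and 0.194 nt over all lengths. Without single variants the difference in mean length ran from 0.542 nt (without Q161) to 1.63 nt (without E37). By length, E. coli enzymes had most in excess at 13 nt (12.3 ± 3.05% against 5.37 ± 3.86%), 22 nt (3.96 ± 3.33% against 0.156 ± 0.213%) and 15 nt (5.81 ± 4.05% against 3.02 ± 3.06%). The A. aeolicus enzymes had most in excess at 11 nt (20.9 ± 4.20% against 11.7 ± 3.03%), 10 nt (10.8 ± 4.02% against 5.55 ± 2.01%) and 12 nt (23.48 ± 9.22% against 20.3 ± 3.32%). The 12 nt excess rests on E64 on FF with its 82 counted reads, since without E64 the A. aeolicus mean was 20.3%. On the log2 odds scale the difference in the 21 to 23 nt share was 3.75 and passed (exact permutation p = 0.0182, adjusted p = 0.0364), where the A. aeolicus values rest on 5 and 2 reads of 21 to 23 nt for Q161 and 0 and 12 for E64. The variants are different proteins and not replicates of one enzyme, and the incubation temperature differed with the enzyme, so that enzyme and temperature cannot be told apart.

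The substrates were compared within each variant. The share of 21 to 23 nt products was lower on MBP than on FF in 8 of 11 variants, by 1.64 ± 2.19 percentage points (SD, n = 11 variants, exact sign-flip p = 0.0254, adjusted p = 0.0508), which did not pass. Over 9 to 25 nt the difference was −1.74 ± 2.28 percentage points (exact p = 0.0225, adjusted p = 0.0449) and passed. The test takes the 11 variants as independent, although several E. coli variants share a substitution and variants are not replicates of one enzyme. Over all lengths it was −2.405 percentage points in the 7 E. coli variants (lower in 6, exact p = 0.0469, adjusted p = 0.0938) and −0.313 in the 4 A. aeolicus variants (lower in 2), and on the log2 odds scale −0.49 for all 11 (exact p = 0.144, adjusted p = 0.287). Without the E. coli E65 table on MBP it was −1.34 percentage points (exact p = 0.0508, adjusted p = 0.102), and without the 4 tables of under 5000 reads −1.39 (exact p = 0.0391, adjusted p = 0.0781). The mean length differed by −0.21 ± 0.72 nt (SD, n = 11, exact p = 0.345, adjusted p = 0.345), and over 9 to 25 nt by −0.09 ± 0.54 nt (exact p = 0.59, adjusted p = 0.59). Over all lengths it was −0.087 nt without the E. coli E65 table on MBP and −0.067 nt without the tables under 5000 reads. The largest gains on MBP were at 11 nt (6.65 ± 8.53 percentage points, higher in 9 of 11 variants), 7 nt (3.73 ± 11.5, higher in 4 of 11, and 0.314 without E. coli E65) and 17 nt (1.39 ± 2.91, higher in 10 of 11, and 0.549 without A. aeolicus E64), and the largest losses at 12 nt (−4.60 ± 10.6, lower in 8 of 11, and −1.90 without A. aeolicus E64), 13 nt (−2.08 ± 4.71, lower in 4 of 11) and 8 nt (−1.91 ± 2.82, lower in 8 of 11).

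Profiles of the same variant on the 2 substrates were closer than profiles of different variants. The FF and MBP profiles of the same variant differed in 21.2% of their reads on average (total variation distance, the share of reads that would have to change length), against 35.6% for profiles of different variants (permutation of the pairing, 100000 resamples, one-sided p = 1e-05, the smallest they can give). Over 9 to 25 nt the distances were 18.7% and 30.3% (permutation p = 4e-05). In all variants but E. coli E38, the FF and MBP tables kept the same shortest length and had the same number, or none, in their names. Variant and any difference in filtering can therefore not be told apart in this test. The 9 to 25 nt window removes only the difference in shortest length. The wild-type E. coli profiles were the closest, at 6.14%, followed by E38 at 11.6%. The A. aeolicus E64 profiles were farthest apart at 48.7%, with 82 counted reads on FF, and the E. coli E65 profiles differed by 45.8% (29.3% over 9 to 25 nt). For 6 of the 11 variants the nearest MBP profile was that of the same variant (4 with cumulative profiles, 3 from 18 nt up). Within the 7 E. coli variants the distances were 20.3% and 29.3% (exact permutation p = 0.000794), and within the 4 A. aeolicus variants 22.9% and 39.6% (exact permutation p = 0.0417). In the 9 to 25 nt window they were 16.8% and 22.8% for E. coli (exact permutation p = 0.0109) and 22.01% and 33.1% for A. aeolicus, which did not pass there (exact permutation p = 0.0833).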

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

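All tests of explanations in this part were chosen after the results had been seen.

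The skipped reads, which no comparison above used, made up a larger share of total reads in 12 tables than in the wild type on the same substrate, with Wilson intervals apart, and a smaller share in 3 (0.044% for E. coli Q165 on FF and no read for A. aeolicus Q161 on either substrate). The intervals cover counting error and not the spread between reactions, so these counts describe the single tables only. For E. coli on FF, where the wild type had 1.40%, the skipped share was 5.13% for E38, 3.97% for E65Q165 (25 reads), 2.61% for EEQ and 1.65% for E65. On MBP, where the wild type had 0.152%, it was 3.54% for EEQ, 1.66% for E65Q165 (19 reads), 1.15% for E38Q165 and 0.308% for E38. For A. aeolicus it was 2.38% (2 reads) for E64 and 0.237% for E37 on FF against 0.015% for the wild type, and 0.278% (8 reads) for E64 and 0.339% for E37 on MBP against 0.074%.

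What the skipped reads are is not stated. Reads over 25 nt are a candidate explanation: the skipped share was higher where the 24 to 25 nt share was higher over the 22 tables (Spearman rho = 0.725, permutation p = 0.00015, adjusted p = 0.000825; Pearson r = 0.695, permutation p = 0.001, adjusted p = 0.00797, and 0.629 without the 2 tables farthest from the median). By rank the relation held in the 14 E. coli tables (rho = 0.855, permutation p = 0.00015, adjusted p = 0.000825; r = 0.736) and in the 11 tables that began at 6 nt (rho = 0.909, permutation p = 0.0003, adjusted p = 0.0011; r = 0.496, permutation p = 0.094), and did not pass in the 8 A. aeolicus tables (rho = 0.368, permutation p = 0.361; r = −0.147).

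Reads below the shortest length a table kept are a candidate explanation too. The skipped share was 1.147 to 5.134% in the 7 tables that began at 8 nt and 0 to 1.402% in the 11 that began at 6 nt (medians 2.609% and 0.144%), but 0.129 and 1.646% in the 2 that began at 7 nt and 0.278 and 2.381% in the 2 that began at 9 nt, with a Spearman rho of 0.717 against the shortest length (22 tables, permutation p = 0.00045, adjusted p = 0.00124; r = 0.64, 0.788 without the farthest 2) and of 0.762 in the E. coli tables (permutation p = 0.00285, adjusted p = 0.00627), while in the A. aeolicus tables rho = 0.634 did not pass (permutation p = 0.105, adjusted p = 0.116). The skipped share was inversely related to the share of 9 to 10 nt products (rho = −0.599, permutation p = 0.0043, adjusted p = 0.00788; r = −0.483), with rho = −0.468 in the E. coli tables (permutation p = 0.0958, adjusted p = 0.116) and rho = −0.743 in the A. aeolicus tables (permutation p = 0.044, adjusted p = 0.0605), neither of which passed after adjustment. In the 11 tables that began at 6 nt it was inverse as well (rho = −0.797, permutation p = 0.00545, adjusted p = 0.00856; r = −0.204, permutation p = 0.505), which argues against reads under 6 nt there, by rank only, for the 3 of the 12 tables that began at 6 nt (E. coli E38 on MBP and A. aeolicus E37 on both substrates). For the other 9, which began at 7 to 9 nt and are mostly of variants with longer products, long reads and reads below the length kept cannot be told apart. They were 11 relations in all, variants are not independent samples, and reads skipped for quality stay open.

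The 21 to 23 nt share of E. coli tables was higher with E38 in 6 of 6 pairs, though at an adjusted p of 0.0625. The difference in the shortest length kept is argued against as its whole cause, since over 9 to 25 nt the mean difference was 6.74 percentage points with an SE of 1.04. Other differences in filtering between the paired tables were not tested. A general shift to longer products that raised 20, 22 and 24 nt alike is argued against as the whole cause for the 4 pairs without E65. There the log2 ratio of 22 nt reads to the mean of 20 and 24 nt, which no length limit changes, was higher by 2.72 on average (SE 0.235, 2.30 to 3.33). The SE takes the 4 pairs as independent, and pairs of one background may share an enzyme preparation. The wild type had a small 22 nt peak too. A shift that also enlarged this peak would raise the ratio, so such a shift stays open. A shift besides the 22 nt product is not excluded. Over 9 to 25 nt the shares at 15, 16, 17, 18, 20, 21 and 24 nt were also higher in 6 of 6 pairs, and the mean length by 1.49 nt. On the E65Q165 background the same ratio changed by −0.221 (SE 0.634, −0.855 on MBP and 0.413 on FF), with 20 and 24 nt counts of 1 to 4 reads in the E65Q165 tables, so a general shift cannot be told apart from a specific 22 nt product there. A slower second cut of 22 nt intermediates by E38 variants may be the reason, as a hypothesis; a few strongly cut sites could give the same peak, and both stay open without positions along the substrate.

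In the E. coli E65 table on MBP, 45.1% of the counted reads were 7 nt long, against 7.20% on FF. On both substrates 7 nt was the shortest length kept for E65, so the excess on MBP lay at the edge of the lengths kept, with 1.23% at 8 nt. Digestion to shorter products in general is argued against, because 8 to 9 nt products made up 5.17% of the 8 to 25 nt reads of E65 on MBP (95% interval 4.92 to 5.43%) against 23.3% for the wild type on MBP. Whether a 7 nt species was in both reactions of this enzyme stays open: on FF the 7 nt share of 7 to 25 nt reads, 7.20%, was above that of the E. coli wild type on FF, 5.57%, but below that of E. coli Q165 on FF, 7.96%, and of the A. aeolicus wild type on FF, 11.03%. A single abundant product, an adapter-derived read or a matching artifact of very short reads stays open too, since sequences are not analysed here.

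The effect of Q165 on the 21 to 23 nt share went opposite ways on 2 backgrounds, lower on both substrates with E38 (mean −4.33 percentage points) and higher on both with E65 (mean 2.99), a gap of 7.32 points. The difference was not tested, as 2 against 2 pairs allow no p under 0.333. Over 9 to 25 nt the gap was 7.12 points.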

How the results depend on the processing

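Over 175 recomputed values of 11 results, 159 kept their call (or, with too few pairs for a test, stayed within 1 SD), 13 crossed to an adjusted p under 0.05 and 3 changed sign in a test. No result that passed was lost, since only the similarity of FF and MBP profiles passed as planned, and it passed under the 5 alternatives, run on 9 to 11 variants; within A. aeolicus alone it did not pass over 9 to 25 nt. The calls for E38 and E65 depend on how many of the 6 tests reach the smallest p of the exact test, 0.03125: all 4 passed (adjusted p = 0.0469) over 9 to 25 nt, a window chosen after seeing the data, with E38 at 1.49 nt and 6.74 percentage points and E65 at 1.46 nt and 5.91 points, and when reads were weighted by nucleotides, with 2.12 nt and 9.96 points, and 1.70 nt and 8.45 points. E38 and E65 kept a positive mean under all alternatives run, including each pair left out in turn. Q165 changed sign for mean length over 9 to 25 nt (−0.184 nt) and from 18 nt up (−0.091 nt), and for the 21 to 23 nt share from 18 nt up (5.37 points). With too few pairs for a test it changed sign in 4 more settings: −0.176 nt without the tables under 5000 reads, −0.323 nt in pairs of equal shortest length, and 0.501 and 0.003 points without the E38 to E38Q165 pair on FF or on MBP. E. coli against A. aeolicus passed from 18 nt up (1.37 nt and 36.1 points), where the A. aeolicus Q161 tables hold 30 and 16 reads and E64 on FF 4, and on the log2 odds scale (3.75), while with the wild types and single variants alone the differences were 0.194 nt and 2.95 points. MBP against FF passed for 20 to 24 nt (−1.92 points) and over 9 to 25 nt (−1.74 points), and not on the log2 odds scale (−0.494). For the E38, E65 and Q165 comparisons, single substrates, the 4 pairs without EEQ and single pairs left out allow no p under 0.05, so they bear on direction only. E. coli against A. aeolicus could have passed on 1 substrate and did not (adjusted p = 0.103 on FF and 0.152 on MBP for the 21 to 23 nt share, exact permutation test). The planned restriction to lengths listed in every table changes nothing, as all list the same lengths, and no wild-type replicate could be left out. No paired analysis was possible because the wild-type tables carry no replicate number, in the sense of pairing by replicate; the pairs tested above match tables by background or variant. Depth limits the E65Q165 and A. aeolicus E64 tables. For the other changes the cause was not tested.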

Other observations

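The tests in this part were chosen after the data had been seen. Products of 15 nt were the only length, among the 17 from 9 to 25 nt, that was higher in all 6 pairs for each of the 3 E. coli substitutions: by 3.84 ± 3.45 percentage points for E38, 3.68 ± 2.95 for E65 and 2.62 ± 1.74 for Q165 (SD, n = 6 pairs each, exact p = 0.03125). Adjusted over the 17 lengths these were 0.059, 0.0664 and 0.531, so none passed. The 15 nt share was 2.16% on FF and 2.85% on MBP for the wild type, and 10.2% and 17.1% for EEQ. For E38, 8 lengths were higher and 1 (10 nt) lower in all 6 pairs, for E65 7 were higher and 1 (10 nt) lower, and for Q165 1 was higher. By chance 0.53 lengths per substitution would be, both directions together, if the 6 pairs are independent. Pairs of one background may share an enzyme preparation, in which case chance gives more. Shares of one table add to a fixed total, so the lengths are not independent. The 3 substitutions share tables, so they are not independent either.

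On MBP, 11 nt products were higher than on FF by 7.07 ± 8.07 percentage points (9 of 11 variants, exact p = 0.00391, adjusted p = 0.0415 over 17 lengths) and 17 nt products by 1.71 ± 3.26 (10 of 11, exact p = 0.00488, adjusted p = 0.0415), both over 9 to 25 nt. Here too the variants were taken as independent, although several E. coli variants share a substitution. Without A. aeolicus E64, whose FF table holds 82 counted reads, the values were 5.06 and 0.906 percentage points (exact p = 0.00781 and 0.00977, n = 10), and neither passed (adjusted p = 0.0554 for both). In A. aeolicus E64 on MBP, 17 nt products made up 9.75% of reads (95% interval 8.72 to 10.9%, 280 reads), against 0.688% for the wild type on MBP.

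Only the E. coli tables with E38, and E65 on FF, E65Q165 and Q165 on MBP, had at least 3.03 times as many reads at 22 nt as the mean of 20 and 24 nt. The ratio was 1.76 and 1.84 for the wild type, 8.70 and 13.1 for E38, 14.2 and 16.02 for E38Q165, and 17.1 and 9.54 for EEQ (FF and MBP), and for E65 it was 3.98 and 0.75. No A. aeolicus table with over 5 reads at 22 nt exceeded 1.09, that of the wild type on FF. A. aeolicus E64 on MBP, with 4 reads at 22 nt, had 2.25. The E65Q165 ratios rest on 1 to 4 reads at each of 20 and 24 nt. All ratios have a small constant added to both parts, which matters where reads are few.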
